A study of Mus musculus with 6 samples.

How the data were processed

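Messenger RNA bound to tagged ribosomes was collected from the cortex of C57BL/6 mice aged 4 months by translating ribosome affinity purification (BAC-TRAP), in which a ribosomal protein, L10a, carries a tag in the cells where a Cre driver is active. The driver here was under the control of the parvalbumin gene. The 6 libraries came as 1 table of whole-number read counts per gene deposited by the authors, with no normalization. Per the submitters' processing notes, CASAVA, Trim Galore 0.6.5, STAR 2.7.3a, HTSeq 0.11.1 and DESeq2 were used with the GRCm38 build. The strand setting, the annotation release, the floxed exons and any pooling of animals are not given in the sources used here; 5 of the 6 library names join a pair of animal-like codes. Unassigned reads in the summary lines of the table were kept out of library sizes and tests.

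Libraries were grouped by their genotype labels: 3 Flox and 2 wild-type libraries listing the Cre driver, and 1 wild-type library listing none, although the series description says that all mice carried the driver. That library was left out of the fit and compared as a single value. Replicate numbers follow the order of deposition. No paired analysis was possible because the labels give no pairs.

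Counts assigned to genes ranged from 19062610 to 25918661 per library. The table held 48795 genes. Reads in no annotated gene made up 14.3% to 15.8%, ambiguous reads 3.97% to 4.55% and reads without a unique position 3.99% to 4.57%. A count of 3 corresponds to 0.116 to 0.157 CPM. Floors cover counting error only. Libraries of a group differed by far more than sampling noise (chi-square per degree of freedom of 11.6 to 19.0), and the biological coefficient of variation was 0.134.

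Positions and exon overlaps came from the GENCODE annotation of GRCm38. Genes were kept by edgeR's filterByExpr, which left 15953, scaled by TMM, and tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test with robust dispersion, 3 residual degrees of freedom and Benjamini-Hochberg correction at 0.05. For simulated counts of this design, the test recovered 46.3% of genes changed 1.5-fold, 64.2% at 2-fold and 89.4% at 4-fold, and called 0.0455% of unchanged genes. Gene lists (32) were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry (limma 3.58.1). Camera with the preset correlation called 16 lists, 7 lower and 9 higher; 0 held with an estimated correlation, with a smallest adjusted p of 0.0976, and fry called 4. Log2 CPM of the single library used a prior count of 2.

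The lists, the main tests and the rule for named genes were fixed before the data were examined. Most tests of other explanations in the closing section, and further genes named there, were chosen after results were seen. Named genes were Esrrg, the 12 with the smallest p in each direction among those passing without overlap of CPM between groups (predicted genes left out), up to 4 members of each list by p, the most abundant markers for the single library, and sex-linked genes. Alternatives changed the normalization (DESeq2 size factors, upper quartile, library size), the low-count filter, the test (DESeq2 1.42.0, limma-voom, other edgeR settings), the threshold, the libraries used and each replicate in turn. After the data were seen, a covariate made of the mean log2 CPM of excitatory neuron, astrocyte, oligodendrocyte and microglia markers was added, as were 2 further fits with the library lacking a Cre driver in its label.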

Results

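Transcripts of 4-month-old mouse cortex were compared between animals carrying a floxed Esrrg gene and wild-type animals, after capture of ribosome-bound RNA aimed at parvalbumin-expressing interneurons. These fast-spiking inhibitory cells fire at high rates, and Esrrg encodes an orphan nuclear receptor (estrogen-related receptor gamma) that acts on genes of energy metabolism. The comparison used 3 Flox libraries and 2 wild-type libraries whose genotype labels list the parvalbumin Cre driver. A further wild-type library, with no Cre driver in its label, was kept apart. Levels are in CPM, the counts of a gene scaled to a common library total. Errors are SD between libraries for CPM and SE of the fit for log2 fold changes (Flox minus wild type).

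Esrrg itself (chromosome 1, 187608791 to 188214885, plus strand, GRCm38) was read at 71.7 ± 12.5 CPM in the Flox libraries (SD, n = 3) and at 80.1 ± 7.66 CPM in the wild type (SD, n = 2). The difference was within the spread between libraries: the log2 fold change was -0.20 ± 0.12, with an adjusted p of 0.535 by edgeR's quasi-likelihood test with Benjamini-Hochberg correction. The libraries overlapped, with 58.7, 83.5 and 72.9 CPM in the Flox libraries and 85.5 and 74.7 CPM in the wild type. Counts were made over the whole gene and the sources used here do not give the floxed exons, so reads from exons left in place would be counted with the rest.

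Across the transcriptome, the Flox libraries had lower levels of parvalbumin, of the GABA-synthesising enzyme Gad1 and of several potassium channel subunits, and higher levels of RNA encoded in the mitochondrial genome. Of 15953 genes tested, 188 passed the test, of which 140 were lower and 48 higher in the Flox libraries. The size exceeded 2-fold for 26 of the lower and 19 of the higher genes. The CPM of all 188 genes did not overlap between the groups; 29.9% of all tested genes did not overlap, where chance gives 20%. The split between lower and higher depended on the scaling: with library size alone 92 genes were lower and 55 higher. Marker lists of other cortical cell types moved with these changes, with medians of 0.30 for excitatory neurons, 0.31 for astrocytes, 0.32 for oligodendrocytes and 0.37 for microglia. Without Flox replicate 1, 2 or 3 the count was 100, 586 or 68, and without wild-type replicate 1 or 2 it was 54 or 59. With a covariate made of those other cell types' markers 24 passed, 6 lower and 18 higher, of which 16 were among the 188, and Kcng4 and Ccdc184 were the only ones of the 140 lower genes left. When the library without a Cre driver in its label was counted as wild type, 0 genes passed in edgeR (318 had an unadjusted p under 0.05), 9 passed in DESeq2 and 17 in limma-voom with library quality weights.

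**Figure D1:**
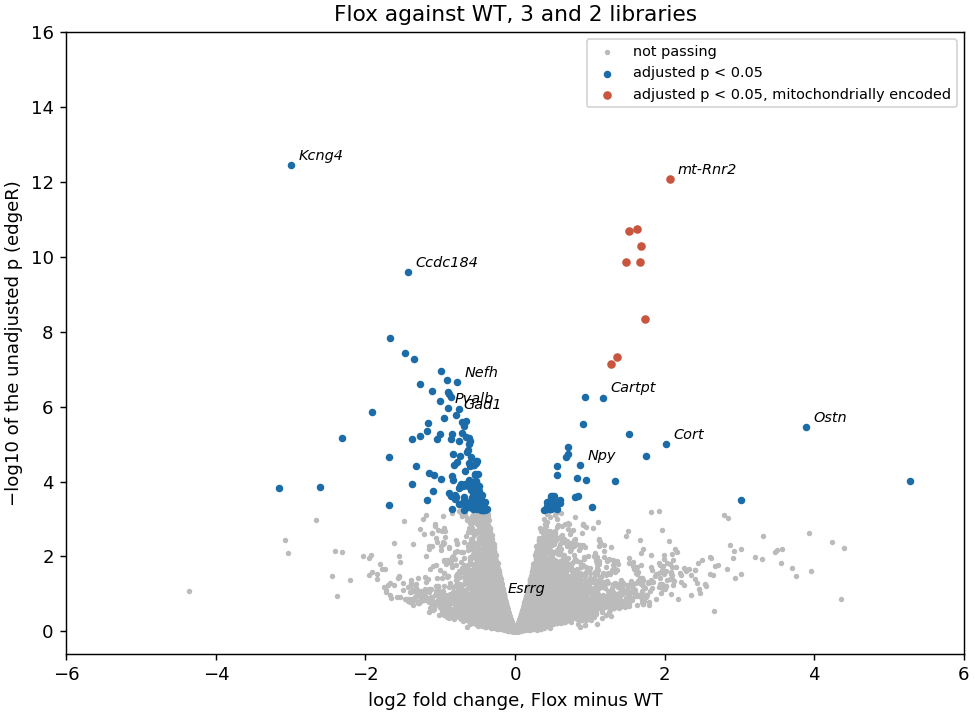
Volcano plot of all tested genes, with the log2 fold change (Flox minus wild type, 3 and 2 libraries) on the x axis and minus log10 of the unadjusted p on the y axis; blue and red points passed the adjusted test, red ones being mitochondrially encoded, and 6 genes lie beyond the axis limit of 6. Kcng4 lies farthest up on the lower side (log2 fold change -3.00), the mitochondrially encoded genes form a group on the higher side, and Esrrg (-0.20) lies among the genes that did not pass.

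The gene with the smallest p was Kcng4, which encodes a modifier subunit of voltage-gated potassium channels. It fell from 53.5 ± 10.8 CPM (n = 2) to 6.86 ± 0.107 CPM (n = 3), a log2 fold change of -3.00 ± 0.15 with an adjusted p of 5.67e-09 by edgeR's quasi-likelihood test. The Flox libraries thus stood near the 7.45 CPM of the library without a Cre driver in its label. Ccdc184 (-1.42 ± 0.11), the centromeric histone variant Cenpa (-1.67 ± 0.17), the sphingosine phosphate phosphatase Sgpp2 (-1.48 ± 0.16) and the kainate receptor auxiliary subunit Neto2 (-1.35 ± 0.13) followed. The other genes of the 12 with the smallest p among those lower were the membrane mucin Parm1 (-0.99), the phosphoinositide phosphatase Inpp5j (-0.91), the heavy neurofilament subunit Nefh (-0.77), the endosomal protein Wdfy1 (-1.27), the intracellular growth factor homologue Fgf11 (-1.12), the potassium channel beta subunit Kcnab3 (-0.90) and the ciliary transport GTPase Ift27 (-0.89). Their adjusted p in edgeR ran up to 0.000339, and each passed in every fit that left out 1 library. With a covariate made of other cell types' markers, Kcng4 (-3.07 ± 0.30) and Ccdc184 (-1.12 ± 0.17) passed and the other genes of the 12 did not, with adjusted p from 0.0977 (Nefh) to 0.611 (Kcnab3). Nefh at -0.74 ± 0.16 and Sgpp2 at -1.37 ± 0.30 lost their calls mainly to wider errors, and Kcnab3 at -0.52 ± 0.16 to a smaller fold as well. With the library without a Cre driver in its label counted as wild type 0 of the 12 passed in edgeR, where Kcng4 stood at -2.50, and in limma-voom with library quality weights Kcng4 passed (-2.89, adjusted p = 0.0281). Sgpp2, Neto2, Inpp5j, Wdfy1 and Kcnab3 each share exon sequence with 1 other annotated gene, and the strand setting of the counts is not given in the sources used here.

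**Figure D2:**
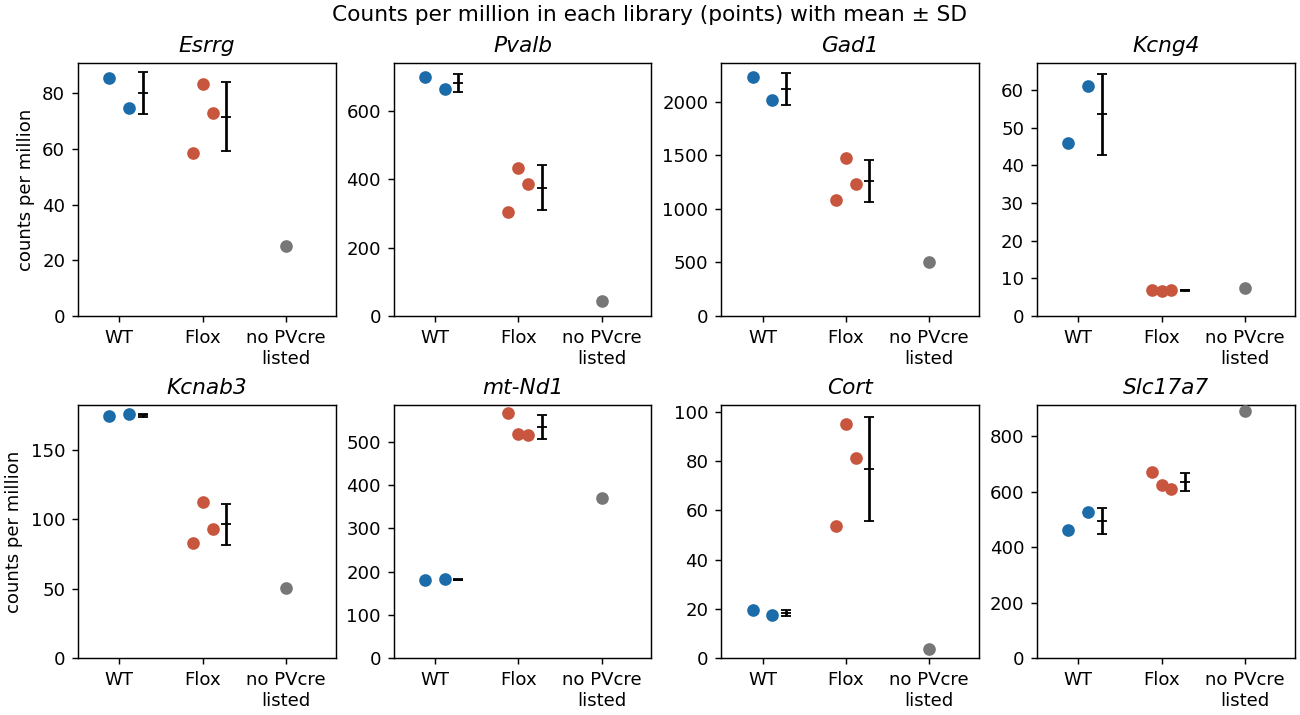
CPM of 8 genes in each library (points) with the mean and SD beside the groups of 2 wild-type and 3 Flox libraries; the grey point is the 1 library with no Cre driver in its label. Esrrg overlaps between the groups, Kcng4 falls from a mean of 53.5 to 6.86, and Cort rises from 18.5 to 76.7.

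Of the 26 tested markers of parvalbumin interneurons, 5 fell and none of the others passed over all genes; adjusted over the list alone, 13 fell. Pvalb, the calcium-binding protein that defines these cells, fell from 682 ± 25.1 CPM to 375 ± 65.9 CPM, a log2 fold change of -0.90 ± 0.12 (adjusted p = 0.000682, edgeR quasi-likelihood). Gad1 fell by 0.79 on the log2 scale, Btbd11 by 0.62, the membrane skeleton ankyrin Ank1 by 0.61 and the fast potassium channel Kcnc1 by 0.52. The list median was -0.32, and camera placed the list below other genes (adjusted p = 7.11e-16, and adjusted p = 0.311 with an estimated correlation). Fry did not call it (adjusted p = 0.153). The markers of excitatory neurons, astrocytes and oligodendrocytes had medians of 0.30, 0.31 and 0.32 in the same libraries. Kcnc1 did not pass without Flox replicate 1 (adjusted p = 0.0836), Flox replicate 3 (0.157), wild-type replicate 1 (0.286) or wild-type replicate 2 (0.163) in edgeR. Ank1 did not pass without Flox replicate 3 (0.0565), wild-type replicate 1 (0.173) or wild-type replicate 2 (0.0772), nor Btbd11 without wild-type replicate 1 (0.065).

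The 7 genes fixed as dependent on the coactivator PGC-1alpha in interneurons, 5 of which also stand in other lists, had a median of -0.77. Inpp5j, Nefh, Pvalb and Cplx1, a complexin of the vesicle fusion machinery, fell, and 6 fell when adjusted over the list alone. The synaptotagmin Syt2, the calcium sensor of fast release, had a log2 fold change of -0.94 ± 0.20 and did not pass (adjusted p = 0.0931, edgeR quasi-likelihood), nor did Ppargc1a, which encodes PGC-1alpha (-0.34, adjusted p = 0.0947). The camera adjusted p of the list was 1.66e-17, and adjusted p = 0.0976 with an estimated correlation. It was also called lower by fry (adjusted p = 0.0464). Among 14 regulators of the estrogen-related receptor and PGC-1 group, 0 passed over all genes and 3 fell when adjusted over the list alone. Esrra (-0.39, adjusted p = 0.123) and Esrrb (-1.07, adjusted p = 0.075), the receptors related to Esrrg, did not pass, and the list's median of -0.07 did not pass either (camera adjusted p = 0.0814). Markers of oligodendrocyte precursors and microglia had medians of 0.48 and 0.37 in the same libraries. Without Flox replicate 2, Syt2 passed (adjusted p = 1.94e-06) and so did Esrra (0.0235). Syt2 also passed in limma-voom (0.0067) and with non-robust dispersion (0.0126), and Ppargc1a in DESeq2 (0.0204). With no low-count filter Syt2 (2.45e-14), Ppargc1a (0.0424), Esrra (0.0172) and Esrrb (0.0296) passed. Cplx1 did not pass without Flox replicate 1 (0.0552), Flox replicate 3 (0.145), wild-type replicate 1 (0.233) or wild-type replicate 2 (0.144).

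Of 25 tested channels that give fast-spiking cells their brief action potentials, 6 fell over all genes; adjusted over the list alone, 11 fell and 3 rose. Kcnab3 fell by 0.90 on the log2 scale, the sodium channel beta subunit Scn4b by 0.65 and the beta subunit Kcnab1 by 0.60. The axonal potassium channel Kcna1 fell by 0.62. The list median was -0.23 (camera adjusted p = 4.33e-10; adjusted p = 0.311 with an estimated correlation), beside a median of 0.30 for excitatory neuron markers. Of 23 genes of synaptic vesicle release, Vamp1, a vesicle membrane SNARE, fell by 0.74 and Cplx1 by 0.62. The list as a whole did not pass in camera, which sets it against other genes (median -0.04, adjusted p = 0.0911). It was called lower by fry, which tests the list by itself (adjusted p = 0.0464). Adjusted over the list alone, 4 vesicle genes fell and 1 rose. Kcna1 did not pass without Flox replicate 3 (adjusted p = 0.0569) or wild-type replicate 2 (0.0971), nor Kcnab1 without wild-type replicate 1 (0.065) or 2 (0.0696), in edgeR.

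Camera with its preset correlation placed both lists of nuclear-encoded subunits of the respiratory chain below other genes, and the mRNAs of the mitochondrial genome, which encodes other subunits of the same complexes, above them. All 37 complex I genes had log2 fold changes below 0, with a median of -0.31; 4 fell over all genes and 28 when adjusted over the list alone. Ndufab1 (-0.52 ± 0.10), Ndufb11 (-0.44 ± 0.10), Ndufa3 (-0.46 ± 0.10) and Ndufb5 (-0.47 ± 0.11) fell. Of 41 genes of complexes II to V, 40 lay below 0 (median -0.31); 6 fell over all genes, among them the ATP synthase subunits Atp5j2 (-0.60), Atp5g3 (-0.47) and Atp5g1 (-0.46) and the cytochrome c oxidase subunit Cox6b1 (-0.54), and 29 when adjusted over the list alone. The camera adjusted p was 2.09e-18 for complex I and 7.98e-20 for complexes II to V, and adjusted p = 0.311 with an estimated correlation for both. Neither list passed in fry (adjusted p = 0.122 for both). Markers of astrocytes and microglia had medians of 0.31 and 0.37 in the same libraries. Each of these 8 named subunits passed without Flox replicate 2. Except Atp5j2, which passed without Flox replicate 1 (0.0265) and without wild-type replicate 2 (0.0467), they failed in each other fit that left out 1 library, with adjusted p in edgeR up to 0.493 for Ndufb5. Other settings ended calls too. With library size alone and with non-robust dispersion Ndufb11 (adjusted p = 0.0591 and 0.0529), Ndufa3 (0.0772 and 0.0651), Ndufb5 (0.0791 and 0.0695), Atp5g3 (0.072 and 0.0506) and Atp5g1 (0.0741 and 0.0554) did not pass, nor with upper-quartile scaling Ndufa3 (0.0615), Ndufb5 (0.0662), Atp5g3 (0.0549) and Atp5g1 (0.0574).

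The 11 tested mRNAs of the mitochondrial genome had a median log2 fold change of 1.67, and 7 rose over all genes and 9 when adjusted over the list alone. The complex I subunit mRNAs mt-Nd1 (1.52 ± 0.10), mt-Nd4 (1.68 ± 0.11), mt-Nd2 (1.67 ± 0.12), mt-Nd6 (1.36) and mt-Nd5 (1.29), the cytochrome oxidase mRNA mt-Co1 (1.48) and the cytochrome b mRNA mt-Cytb (1.74) rose. The mitochondrial ribosomal RNAs rose too, mt-Rnr2 by 2.07 ± 0.11 and mt-Rnr1 by 1.63 ± 0.10. Mitochondrially encoded RNA made up 0.612%, 0.568% and 0.512% of counts in the Flox libraries, 0.172% and 0.155% in the wild type, and 0.4% in the library with no Cre driver in its label. Capture by the tag is therefore not shown for these RNAs. The camera adjusted p was 7.35e-71, and adjusted p = 0.0976 with an estimated correlation. Fry called the list higher (adjusted p = 0.0464). The median of oligodendrocyte precursor markers was 0.48. All 9 named RNAs passed in edgeR in each fit that left out 1 library, and with the covariate of other cell types' markers all passed but mt-Nd6 (adjusted p = 0.0873).

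The other genes of the 12 with the smallest p among those higher were Bex1 (0.94 ± 0.12), the neuropeptide precursor Cartpt (1.18 ± 0.15) and the reticulocalbin Rcn1 (0.90 ± 0.13), a calcium-binding protein of the secretory pathway. Cartpt rose from 15.5 ± 1.08 CPM to 36.0 ± 5.90 CPM. Of 20 genes of the integrated stress and unfolded protein responses, 2 rose over all genes, and 8 rose and 2 fell when adjusted over the list alone. They were the stress transcription factor Atf4 (0.56 ± 0.11) and the mitochondrial folate enzyme Mthfd2 (0.80 ± 0.17). The list median was 0.29 (camera adjusted p = 0.00335; adjusted p = 0.311 with an estimated correlation). Astrocyte markers, with a median of 0.31, moved the same way. Without wild-type replicate 2, Rcn1 (adjusted p = 0.0601) and Atf4 (0.251) did not pass in edgeR, and Atf4 did not pass without wild-type replicate 1 (0.065). Mthfd2 passed only without Flox replicate 2, with adjusted p of 0.143, 0.0816, 0.36 and 0.152 without Flox replicates 1 and 3 and wild-type replicates 1 and 2.

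Camera with its preset correlation placed the marker lists of excitatory neurons, glia and vessel cells above other genes, and called no list of a further cell type other than the captured one. Among 15 excitatory neuron markers, all above 0, the postsynaptic calmodulin-binding protein Nrgn rose by 0.69 ± 0.12, and the vesicular glutamate transporter Slc17a7 had a log2 fold change of 0.32 (adjusted p = 0.123, edgeR quasi-likelihood; 0.0247 in DESeq2); 4 rose when adjusted over the list alone. Among 13 astrocyte markers, led by the glutamate transporters Slc1a3 (0.44) and Slc1a2 (0.42), 0 passed; without Flox replicate 2 (adjusted p = 0.00638 and 0.0053) or a low-count filter (0.00631 and 0.00451) both did, and Slc1a2 did in DESeq2 (0.0456). The 13 oligodendrocyte markers included the myelin gene Cnp (0.32), and 0 passed over all genes and 4 rose when adjusted over the list alone. Of 7 precursor markers 3 rose when adjusted over the list alone, and of 12 microglia markers and 12 endothelial and mural markers 0 did. The camera adjusted p was 1.30e-06 for excitatory neurons, 4.49e-05 for astrocytes, 2.44e-05 for oligodendrocytes, 0.00505 for their precursors, 0.000399 for microglia and 0.0485 for endothelial and mural cells. With an estimated correlation the adjusted p was 0.311, 0.424, 0.311, 0.311, 0.385 and 0.369 in the same order. Nrgn did not pass without wild-type replicate 1 (0.065) or 2 (0.146). The endothelial list did not pass without Flox replicate 1 (0.0541), Flox replicate 3 (0.184) or wild-type replicate 2 (0.339).

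**Figure D3:**
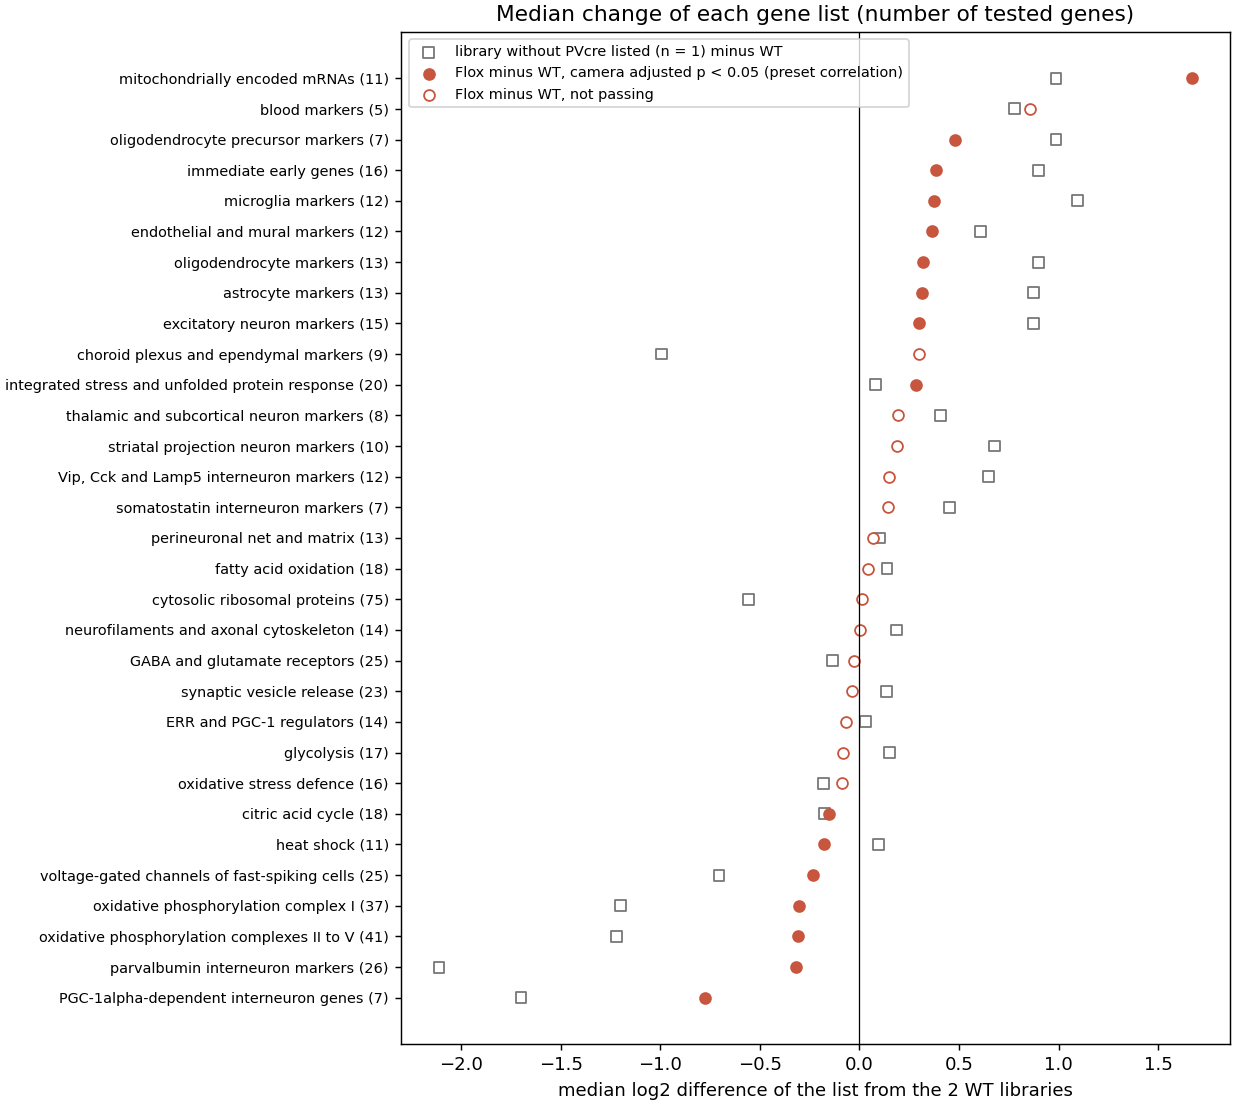
Median log2 difference from the 2 wild-type libraries on the x axis for 31 gene lists (number of tested genes in brackets); circles are the Flox libraries, filled where camera with the preset correlation passed, and squares are the 1 library with no Cre driver in its label. Parvalbumin markers (-0.32) and complex I (-0.31) lie on the lower side and the mitochondrially encoded mRNAs (1.67) on the higher side in the Flox libraries.

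Among the remaining lists, citric acid cycle genes (median -0.15, camera adjusted p = 0.00939; adjusted p = 0.361 with an estimated correlation) and heat shock genes (median -0.18, 0.00309; adjusted p = 0.357 with an estimated correlation) were placed below other genes, with 0 members passing over all genes and 4 and 1 lower when adjusted over the list alone. The pyruvate dehydrogenase subunit Pdhb (-0.37) and the cochaperone Bag3 (-0.59) had the smallest p of each, and both passed in DESeq2 (adjusted p = 0.00315 and 0.0437) and with no low-count filter (0.0167 and 0.0336), and Pdhb without Flox replicate 2 (0.036). Immediate early genes, which respond to neuronal activity, had a median of 0.38 with all 16 above 0 and 0 passing (camera adjusted p = 0.00138; adjusted p = 0.499 with an estimated correlation). The citric acid cycle list did not pass without wild-type replicate 2 (0.239), and the immediate early list did not pass without Flox replicate 3 (0.346) or wild-type replicate 2 (0.0522). Lists that camera did not call were glycolysis (median -0.08), fatty acid oxidation (0.04), oxidative stress defence (-0.09), receptors for GABA and glutamate (-0.03), somatostatin interneurons (0.14), interneurons marked by Vip, Cck and Lamp5 (0.15), striatal projection neurons (0.19), thalamic and subcortical neurons (0.19), blood (0.85) and ribosomal proteins (0.01). The somatostatin list was called higher by fry (adjusted p = 0.0464). Within them the peroxiredoxin Prdx5 (-0.49) fell and the neuropeptide Cck (0.42) rose over all genes, and both passed in edgeR only without Flox replicate 2 among the fits that left out 1 library, with adjusted p up to 0.439 and 0.341 in the others. Cck did not pass with non-robust dispersion (0.0572) either. Camera's direction was down, without a call, for perineuronal net genes (median 0.07, mean -0.13), neurofilaments (median 0.005, mean 0.01) and choroid plexus markers (median 0.30, mean 0.16), and none of the 3 had its direction in common with its median. Leaving out 1 library brought camera calls in lists that otherwise had none, some in opposite directions. Without Flox replicate 1 the regulators of the receptor and coactivator group (median -0.23, adjusted p = 0.0117), glycolysis (-0.09, 0.0169), choroid plexus (-1.30, 0.00143) and blood (-0.59, 0.00138) were called lower. Blood was called higher without Flox replicate 2 (1.17, 0.0243) or 3 (1.24, 0.00972), and receptors for GABA and glutamate lower without Flox replicate 2 (-0.09, 0.0411). Without wild-type replicate 1 glycolysis was called lower (-0.13, 0.00496), and striatal neurons (0.60, 2.41e-05), ribosomal proteins (0.13, 1.24e-05) and sex-linked transcripts (8.84, 1.79e-28) higher. Without wild-type replicate 2 ribosomal proteins (-0.09, 0.0123) and sex-linked transcripts (-0.79, 0.00235) were called lower. In the neurofilament list Nefh fell over all genes.

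The library labelled wild type without a Cre driver had low levels of parvalbumin-cell transcripts beside the 2 other wild-type libraries. As 1 library it allowed no test. Pvalb stood at 45.5 CPM against 682 ± 25.1 CPM and Gad1 at 500 CPM against 2119 ± 152 CPM. The parvalbumin list had a median log2 difference of -2.11, at percentile 0 of 10000 random lists matched on expression, and complex I had a median of -1.20. The excitatory neuron genes Camk2a (1978 CPM against 1447) and Slc17a7 (890 against 495), the astrocyte transporter Slc1a2 (1148 against 608), the myelin gene Mbp (1918 against 1052) and the microglial complement gene C1qb (49.1 against 21.4) were higher. Their lists had medians of 0.88, 0.87, 0.90 and 1.09, each at percentile 100. Esrrg stood at 25.1 CPM in this library. Markers of other cells, such as Camk2a at 1447 CPM, were well read in the 2 other wild-type libraries too. Levels in the captured RNA thus do not stand for parvalbumin cells alone.

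Transcripts linked to sex differed between libraries within a genotype. Wild-type replicate 2 had 0 counts of Ddx3y, Eif2s3y, Kdm5d and Uty, which lie on the Y chromosome; 0 counts allow up to 0.116 CPM for each. Ddx3y was read at 25.3, 26.8 and 10.6 CPM in Flox replicates 1 to 3 and at 32.1 CPM in wild-type replicate 1. Xist, the transcript of the inactive X chromosome, was read at 1.24, 1.82 and 4.77 CPM in the Flox libraries and at 2.78 and 2.89 CPM in the wild type. The library with no Cre driver in its label had 99.2 CPM of Ddx3y and 0 counts of Xist. The labels do not give sex, and none of the sex-linked genes passed by genotype (adjusted p from 0.929 to 0.992 in edgeR). For the Y genes that test could not decide, since the wild-type libraries ranged from 0 counts to 32.1 CPM of Ddx3y. Transcripts of the Y chromosome were read in all 3 Flox libraries but in only 1 of the 2 wild-type libraries. The groups were thus not balanced for RNA from males.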

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

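The covariate of other cell types' markers, and the DESeq2 and quality-weighted limma-voom fits with the library lacking a Cre driver in its label counted as wild type, were chosen after the data were seen. The 188 main calls kept their sign in each fit that left out 1 library. Since their CPM did not overlap between the groups, this was nearly fixed beforehand and lends the calls no support. The count of genes passing (lower, higher) ranged from 54 to 586 (34 to 421, 17 to 165) in those fits, where a lone wild-type library is assumed to vary like the others. It was 577 (405, 172) without a low-count filter, 441 in DESeq2 (69.6% lower, 134 higher) and 390 (288, 102) at a threshold of 0.1. Library size alone gave 92 lower, and non-robust dispersion 31 higher. With the covariate 24 passed (6, 18). With the added library 0 passed in edgeR (0, 0), where 318 had an unadjusted p under 0.05, 9 in DESeq2 (0, 9) and 17 in limma-voom (1, 16). Esrrg turned to 0.20 with the added library in edgeR, 0.19 in DESeq2 and 0.24 with the covariate, and Esrra to 0.0034 with the added library in edgeR. Slc1a3 turned to -0.17 and Slc1a2 to -0.0894 with the covariate, which holds both, and Cnp to -0.0230 with the added library in edgeR and -0.0323 in DESeq2.

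Camera's calls of lists (lower, higher) went from 16 (7, 9) to 0 (0, 0) with an estimated correlation, to 4 (2, 2) in fry, to 5 (2, 3) with the added library and to 15 to 20 (7 to 11, 7 to 12) in fits that left out 1 library. With the added library the test or the median turned for parvalbumin markers (median 0.15), complex I (-0.0091), fast-spiking channels (-0.0178), excitatory neurons (-0.0173), astrocytes (0.0056), oligodendrocytes (-0.0230) and microglia (-0.0316). The added library's own low parvalbumin and high marker levels pull the wild-type mean that way by construction. Against all 5 libraries listing the driver, the parvalbumin median of the single library moved from -2.11 to -1.98. The medians moved from 0.88 to 0.64 for excitatory neurons and from 0.87 to 0.66 for astrocytes. They moved from 0.90 to 0.71 for oligodendrocytes and from 1.09 to 0.87 for microglia. The other causes were not tested.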

Other observations

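The gene groups in the opening paragraph and all tests of a share of other cells' RNA and of Cort and Npy were chosen after the result was seen; the count over other splits of the libraries and the test of genes near Esrrg were not. The tests also have a history. For the lists, the first test asked whether other cell types' lists rose alike, and the covariate tests were added once its result was known, for 2 lists first and for the other lists that camera called lower after all values had been seen. They first set list medians against the error of single genes, which is not the error of a list, and were redone on list means with the error between libraries. The first test was labelled as arguing against a lower share until the same lists were compared in the library with no Cre driver in its label. For Kcng4, the first test counted genes below Pvalb, and the gene was singled out from that count. For mitochondrial RNA, the first test could not decide, and the covariate value had been seen when it was added as a test, whose label now rests on the mRNAs that passed.

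Of the 48 genes called higher, 9 were lower in the library with no Cre driver in its label than in the wild type, among them Cartpt, Atf4 and the genes below. Cort, the somatostatin-like peptide cortistatin, rose from 18.5 ± 1.27 CPM (n = 2) to 76.7 ± 21.2 CPM (n = 3), a log2 fold change of 2.02 ± 0.22 (adjusted p = 0.00308, edgeR quasi-likelihood), and stood at 3.53 CPM in the single library. Npy (neuropeptide Y) rose by 0.87 ± 0.14, the peptide hormone gene Ostn by 3.89 ± 0.57 from 5 and 3 counts in the wild type, the galectin Lgals1 by 1.33 ± 0.20 and Mustn1 by 1.52 ± 0.23. Cort did not pass without wild-type replicate 1 (0.127) or 2 (0.146), and Npy not without Flox replicate 3 (0.0526) or wild-type replicate 1 (0.127) or 2 (0.15). Lgals1 did not pass without Flox replicate 2 (0.0636) or wild-type replicate 1 (0.187) or 2 (0.206), and Mustn1 not without wild-type replicate 2 (0.0696). DESeq2 on the 5 libraries gave no adjusted p for Ostn.

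Of the 10 splits of the 5 libraries into 3 and 2, 1, the real one, gave as many as 188 genes; the highest other gave 41, and 10 splits are too few for a share under 0.05. Within 10 Mb of Esrrg, 1 of 129 tested genes passed (Cnih3, 0.51) where 1.52 would be expected. Calls were thus not enriched in that window. The count does not cover a longer strain segment, or effects of a strain difference on genes elsewhere, so these stay open. Cnih3 did not pass in limma-voom (adjusted p = 0.0535), with non-robust dispersion (0.0554), or without Flox replicate 1 (0.146) or wild-type replicate 1 (0.322) or 2 (0.243).

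Lower lists of parvalbumin markers and the respiratory chain beside higher lists of other cell types may reflect a lower share of parvalbumin-cell RNA in the Flox libraries, and most tests of this hypothesis did not decide. The first decided nothing: the 8 lists of other types all had medians above 0 (0.14 to 0.48) and differed from each other (permutation p = 0.0074, Kruskal-Wallis statistic, genes permuted). The same lists also differed in the library with no Cre driver in its label (medians 0.45 to 1.09, permutation p = 0.0013, Kruskal-Wallis statistic, genes permuted), so a lower share need not raise them alike. Genes of a list are correlated, which makes both p too small, and the second describes 1 library only. With the marker covariate the difference in the list mean (SE between libraries, 2 residual degrees of freedom) went from -0.22 ± 0.09 to 0.00093 ± 0.03 for fast-spiking channels, which fits a lower share. For the other lists called lower the test did not decide. The mean went from -0.36 ± 0.14 to -0.0259 ± 0.08 for parvalbumin markers, from -0.30 ± 0.09 to -0.14 ± 0.13 for complex I and from -0.30 ± 0.10 to -0.11 ± 0.13 for complexes II to V. It went from -0.64 ± 0.10 to -0.39 ± 0.06 for the PGC-1alpha-dependent genes (adjusted p = 0.146 over the 7 lists, t test of the fit), from -0.11 ± 0.03 to -0.13 ± 0.07 for the citric acid cycle and from -0.20 ± 0.08 to -0.19 ± 0.17 for heat shock. Pvalb went from -0.90 ± 0.12 to -0.46 ± 0.15, which ended its call by a smaller fold and a wider error. The covariate, at 5.08 and 5.08 in the wild type and 5.55, 5.22 and 5.40 in the Flox libraries, separates the genotypes and would take up a genotype effect too. A share lowered alike for all parvalbumin cells could not be the whole account of Kcng4. Of the tested genes 1 lay below Pvalb beyond the errors, and this was Kcng4, by -2.10 ± 0.19. A change in a subset of parvalbumin cells could lower Kcng4 more than Pvalb and stays open. For the lists, a lower share and an effect of the genotype within the cells both stay open.

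Higher mitochondrially encoded RNA was tested against the same lower share. In the first test 11 of 11 mRNAs lay above the library with no Cre driver in its label in all 3 Flox libraries, which 1 library cannot turn into evidence. With the covariate the median went from 1.67 to 1.40 and 6 of the 11 still rose over all genes, among them mt-Nd1 at 1.38 ± 0.14, which argues against a lower share as the whole cause. The list mean, with 2 residual degrees of freedom, was 1.35 ± 0.35 and decided nothing by itself. Mitochondrially encoded RNA also made up 0.4% of counts in the library with no Cre driver in its label. The tagged protein, L10a, is a part of cytosolic ribosomes, whereas these RNAs belong to the mitochondrial genome. The values therefore do not show that these RNAs came from the tagged ribosomes, and their rise cannot be read as translation in parvalbumin cells. A difference in tissue handling or capture between genotypes was not tested, since the labels give no batch, and an effect of the genotype stays open.

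More RNA from somatostatin interneurons could raise Cort and Npy. Cort rose beyond Sst, the defining peptide of those cells, by 1.84 ± 0.25 and Npy by 0.70 ± 0.18, and Sst itself had a log2 fold change of 0.17 (adjusted p = 0.566, edgeR quasi-likelihood), which argues against that source. Of the 7 somatostatin markers, 1 also stands in another list and 0 passed. An effect of the genotype, and a change in a subset of those cells, stay open.

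The directions of the 188 calls matched those of the library with no Cre driver in its label for 94.7%. In 20 simulations with no effect but the same shared wild-type libraries the match averaged 91.1%, with a highest of 94.1%. They drew the single library from the wild-type mean, although the real one differed from the wild type (parvalbumin list median -2.11). Independent directions would give 48.7%, a value that leaves out the shared wild-type libraries. Neither value is a matching baseline, so the match decides nothing. Ttr, a choroid plexus transcript, stood at 570 CPM in Flox replicate 1 and 200 CPM in wild-type replicate 2, and between 5.61 and 23.3 CPM in the other libraries.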
